A study of Mus musculus with 24 samples.

How the data were processed

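RNA was sequenced from mouse bone marrow macrophages that had been expanded on petri dishes and then kept in macrophage colony-stimulating factor (M-CSF) alone or in M-CSF with receptor activator of NF-κB ligand (RANKL), the cytokine that drives macrophages to fuse into bone-resorbing osteoclasts. Per the labels' protocols, 15000 cells were seeded per well, the medium for osteoclasts held RANKL at 50 ng/mL with M-CSF at 30 ng/mL, and 250 ng of total RNA per library entered a TruSeq RNA kit. The M-CSF dose of the wells without RANKL and the strand setting of the kit and of the counting are not given in the sources used here. The control cells carried a Runx1 transgene at the Rosa26 locus without Cre, and the other cells carried the same transgene together with Cre driven from the lysozyme 2 gene (LysM-Cre), which is active in myeloid cells and is meant to switch the transgene on. The labels call the first wild type control and the second Runx1 gain of function. The 24 libraries form 8 groups of 3, from 2 genotypes, 2 media and days 3 and 5. Each label carries a number from 1 to 3, and no label says whether the number marks an animal, a culture or a day, nor the sex of the mice. The p-values therefore measure only the spread between these samples, part of which may be technical.

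The authors deposited a single table of whole-number read counts per gene for all libraries, with a gene identifier, a symbol and a position for each of 54532 genes. The submitters' processing notes name STAR, DESeq2 and the build GRCm39, and the versions and the counting settings are not given in the sources used here. The positions were checked against the GENCODE M21 annotation of GRCm38. Of the identifiers, 54495 were found there, and 53548 of these (98.3%) had the same chromosome, start and end, so positions are given as the deposited table gives them and match GRCm38 rather than the build named in the notes. In the table, 105 symbols occur more than once. Every value column was matched to a library by its title, and 0 columns stayed unmatched.

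Tests were run on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 15035 of the genes (27.6%), and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 24 libraries with a coefficient per group, so that the groups shared an estimate of the spread. Differences were called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p in the text is from this test unless another is named. Standard errors (SE) were derived from the fitted log2 fold change and its F statistic, and intervals are at 95%. Counts were also expressed as CPM, the share of the TMM-scaled library size in parts per 1e6, and are given as mean ± SD over 3 libraries. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group. Such bounds cover counting error only.

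The comparisons were genotype within each day and medium, RANKL against M-CSF alone within each day and genotype, day 5 against day 3 under RANKL within each genotype, and the differences of these responses between genotypes. Gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists that had at least 5 tested members, and again with the correlation estimated for each list. There were 27 lists with 500 symbols, of which 499 were in the table, and 24 lists had enough tested members. They cover osteoclast resorption, osteoclast regulators, osteoclastogenesis inhibitors, ITAM costimulation, V-ATPase and lysosome, macrophage, alternative activation, MHC class II and dendritic, interferon-stimulated, inflammatory NF-κB, cell cycle, apoptosis and survival, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, LXR and lipid efflux, Runx family and partners, progenitor, monocyte, neutrophil granule, mast cell and basophil, stromal and osteoblast, lymphoid, erythroid and megakaryocyte, stress and immediate early, sex-linked, and transgene locus genes. The lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined.

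The rule for naming genes had several parts. For genotype and RANKL comparisons these were the 12 largest rises and the 12 largest falls among genes past the threshold with an average log2 CPM of at least 1, a symbol that is not that of a predicted gene, and no overlap between the 3 values of each group. For day comparisons and differences of responses the number was 6 in each direction. Runx1, Cbfb, Lyz2, Gt(ROSA)26Sor and the sex-linked genes were taken in each comparison, as were up to 4 members of each list with the smallest p. Nectin1 and the genes named for counts of calls obtained with other tools or fewer libraries were chosen after their values were seen. Genes with near-identical copies, such as Lyz1 and Lyz2, and genes that overlap another or have an antisense partner are uncertain, because the counting settings are not given in the sources used here.

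The alternatives were the Wald test of DESeq2 1.42.0 with its own size factors, RLE scaling in edgeR, no filter beyond a single read, a fit to the compared groups alone, the label number as an additive block, an estimated correlation for the lists, and each library left out in turn. The block was the number shared across genotypes for the genotype comparisons, and the number within a genotype for all others. Leaving out all 4 libraries of a number in a genotype was added after the data were seen, because the 4 libraries of number 3 labelled Runx1 overexpression carried Y-linked transcripts. Leaving out a number in both genotypes was added later still. Whether the numbers pair libraries across groups was checked by correlating the deviations of same-numbered libraries from their group means, before any blocked result was looked at. All 3 correlations exceeded 0.1 only for RANKL at day 5 in the libraries labelled Runx1 overexpression, where they ran from 0.166 to 0.369. Within a genotype, however, each library correlated best with the library of its own number in every comparison checked. These hints of pairing come from the data and not from the labels, and no main fit treated libraries as paired.

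The pipeline was tested on simulated counts with the real means and library sizes and 100 genes at each of 2 fold sizes. For genotype at day 5 under RANKL it recovered 65% of genes changed 2-fold and 81% of genes changed 4-fold, with 3 false calls among 14524 genes. For RANKL at day 3 in controls it recovered 57% and 81% with 7 false calls among 14547 genes. For the difference of RANKL responses at day 5 it recovered 42% and 69% with 4 false calls among 14573 genes, and for day in controls 58% and 77% with 4 false calls among 14553 genes. In each case 0 of 20 unchanged lists were called and the changed list was called. The simulated genes were drawn independently, from a single mean per gene apart from the set changes, and the unchanged lists were random genes. Real lists were correlated, with an estimate of 0.852 for cholesterol synthesis with RANKL at day 3 in control cells. The simulation therefore does not test the preset correlation. It also lacks any structure between libraries, so its recovery and false calls may not hold for the real counts. Replicate libraries were also compared for duplicates. The chi-square per gene over the 24 pairs within groups ran from 3.37 to 109, so every pair differed by more than sampling noise.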

Results

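Gene expression was measured by RNA-seq in macrophages grown from mouse bone marrow and in the osteoclasts that formed from them under RANKL. Control cells carried a Runx1 transgene at Rosa26 without Cre, and the cells labelled Runx1 overexpression carried the same transgene with Cre driven from Lyz2, the lysozyme gene of myeloid cells. Runx1 is a transcription factor of blood cell development that binds DNA together with its partner Cbfb. Both genotypes were sampled at days 3 and 5, with M-CSF alone or with M-CSF and RANKL, in 3 libraries per group and 24 in all. Library totals, in 1e6 counts, ran from 20.3 to 23.5 in control cells at day 3 in M-CSF alone, from 19.8 to 23.9 at day 3 with RANKL, from 19.1 to 20.8 at day 5 in M-CSF alone and from 21.4 to 22.3 at day 5 with RANKL. In the cells labelled Runx1 overexpression the ranges in the same order were 22.4 to 24.3, 20.5 to 24.2, 21.1 to 23.7 and 19 to 36.5, the last set by library number 3. A single read was worth 0.0286 to 0.0542 CPM. Mitochondrial transcripts took 1.69% ± 0.0805 (SD, n = 3) of counts in control cells at day 3 in M-CSF alone and 3.65% ± 0.438 with RANKL, and 1.94% ± 0.446 and 3.89% ± 0.662 in the cells labelled Runx1 overexpression. Of the variance between libraries, 67.4% lay on a first principal component and 10.2% on the second.

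Runx1 itself (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149, protein coding) was measured first, because it checks the genotype labels. Its level was 79.4 ± 12.8 CPM in control cells and 86.0 ± 11.7 CPM in the cells labelled Runx1 overexpression at day 3 in M-CSF alone, and 106 ± 11.9 against 106 ± 3.97 CPM at day 5 (SD, n = 3 in each group). With RANKL the levels were 51.5 ± 0.862 against 57.9 ± 8.23 CPM at day 3 and 68.6 ± 2.56 against 80.6 ± 15.1 CPM at day 5. The log2 differences between genotypes were 0.12 (interval −0.17 to 0.40), 0.00 (−0.28 to 0.29), 0.17 (−0.12 to 0.45) and 0.23 (−0.05 to 0.51) in that order, with an adjusted p of 1 in each. The labels call for a higher level, and none of these intervals reached a doubling. Whether reads of the transgene can be counted at Runx1 is not given in the sources used here. These libraries are therefore called the libraries labelled Runx1 overexpression throughout. Transcripts of Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333), which marks the locus of the transgene, lay between 5.90 and 9.04 CPM in the control groups. Lyz2 (chromosome 10, 117277331 to 117282321), the site of the Cre insertion, differed by −0.60, −0.67, −0.38 and −0.35 log2 units at day 3 in M-CSF alone, day 3 with RANKL, day 5 in M-CSF alone and day 5 with RANKL (SE 0.29 each, adjusted p 1, 1, 0.892 and 1). The 4 libraries of number 3 labelled Runx1 overexpression carried 2576 counts from the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in total. The other 5 numbered sets of 4 libraries carried 0 to 2 such counts each. The X-linked gene Xist had 2 to 12 counts in each library of that number 3 and 14963 to 28379 in each other library. Number 3 thus has the pattern of male cells and the other sets that of female cells, though no label gives the sex.

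**Figure D1:**
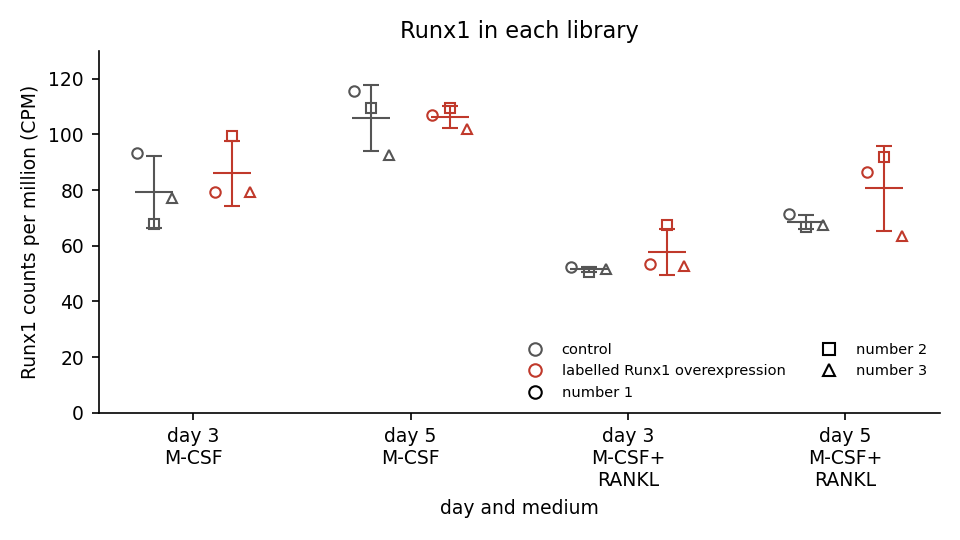
Runx1 counts per 1e6 counts (CPM, vertical axis) in each of the 24 libraries by day and medium (horizontal axis), with grey for control, red for libraries labelled Runx1 overexpression and marker shape for the number in the label; long bars are means and whiskers are the SD of 3 libraries. Mean levels with M-CSF alone run from 79.4 to 106 CPM and with RANKL from 51.5 to 80.6 CPM, and the values of the genotypes overlap or lie close in each condition.

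The comparison of RANKL with M-CSF alone shows what differentiation did in each genotype. At day 3, control cells given RANKL had taken on the transcripts of bone-resorbing cells. Ctsk, the protease that degrades bone collagen, rose from 3.99 ± 1.69 to 10231 ± 1781 CPM (log2 fold change 11.33, SE 0.30, adjusted p = 2.44e-16), and Mmp9, a matrix metalloproteinase, from 9.01 ± 1.55 to 23742 ± 4115 CPM (11.36, SE 0.31). The acid phosphatase Acp5 rose by 9.65 log2 units (SE 0.29), the integrin Itgb3 by 7.90 (SE 0.38) and the fusion protein gene Dcstamp by 9.86 (SE 0.34). The receptors Oscar and Calcr and the actin-severing protein gene Scin had 0 counts in M-CSF alone and rose at least 6437-fold, 3245-fold and 7760-fold. Surface markers of macrophages fell at the same time. The mannose receptor Mrc1 went from 2495 ± 363 to 124 ± 40.6 CPM (−4.32, SE 0.32), the scavenger receptor Cd36 changed by −3.78 (SE 0.14) and the sialic acid receptor Siglec1 by −5.80 (SE 0.59). In total 8888 of 15035 genes passed, 4428 higher and 4460 lower, of which 2430 and 2425 changed more than 2-fold.

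Among the fixed lists at day 3 in control cells, 21 of the 22 osteoclast resorption genes rose and 0 fell (21 adjusted over the list alone), with a median of 7.33 log2 units that stays at 7.33 when genes with 0 counts are set to their bounds. The list test gave an adjusted p = 9.91e-55, and adjusted p = 0.000672 with an estimated correlation. The member that did not pass was Plekhm1, a lysosomal adaptor, at 0.23 (SE 0.16, adjusted p = 0.241). Of 22 osteoclast regulators, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with an adjusted p = 8.35e-08 and adjusted p = 0.0157 with an estimated correlation. Nfatc1, the master transcription factor of osteoclasts, rose 8.16-fold, and the AP-1 factors Fosl2 and Jdp2 rose 25.9-fold and 61.5-fold. All 24 oxidative phosphorylation genes rose (24 adjusted over the list alone, median 1.45, adjusted p = 1.08e-21; adjusted p = 0.0846 with an estimated correlation), among them the complex I gene Ndufv1 at 3.87-fold and the complex III gene Uqcrc2 at 4.95-fold. The list of proton pump and lysosome genes split. Of its 20 members 14 rose and 6 fell, over all genes and adjusted over the list alone (adjusted p = 0.00471; adjusted p = 0.644 with an estimated correlation). The pump subunit gene Atp6v1b2 rose 7.93-fold, while the cathepsin gene Ctsd, which encodes a lysosomal protease, was among those that fell, from 4936 ± 562 to 1330.1 ± 257 CPM.

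Of 20 macrophage genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone, adjusted p = 1.62e-10; adjusted p = 0.145 with an estimated correlation). Of 28 interferon-stimulated genes, 23 fell and 0 rose (23 and 0 adjusted over the list alone, median −2.26, adjusted p = 0.00069; adjusted p = 0.829 with an estimated correlation), including the antiviral tetherin gene Bst2 at −2.36 (SE 0.20). In the list of ITAM costimulation, the adaptor signals that accompany RANKL, 10 of 15 genes fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.00912; adjusted p = 0.442 with an estimated correlation). The lipid receptor Trem2 fell by 2.95 and the Fc receptor Fcgr3 by 3.79 log2 units. Of 30 cell cycle genes 22 fell and 0 rose (22 and 0 adjusted over the list alone, adjusted p = 0.000502; adjusted p = 0.829 with an estimated correlation), with the proliferation marker Mki67 at −1.41 (SE 0.23, adjusted p = 2.73e-05). Of 21 cholesterol synthesis genes 14 fell and 0 rose (16 and 0 adjusted over the list alone, adjusted p = 0.0439; adjusted p = 0.829 with an estimated correlation). Runx1 fell by 0.62 log2 units (SE 0.14, adjusted p = 0.000523) and Cbfb by 0.72 (SE 0.16, adjusted p = 0.000515). Lyz2 fell from 20661 ± 4591 to 3034 ± 1064 CPM, and the clotting factor gene F13a1, a monocyte marker, fell by 5.93.

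The remaining lists did not pass at day 3 in control cells, with adjusted p between 0.116 and 0.958. Their members that rose and fell numbered 6 and 5 of 15 osteoclastogenesis inhibitors, 2 and 4 of 9 genes of alternative activation (3 and 5 adjusted over the list alone), 7 and 5 of 19 MHC class II and dendritic genes (9 and 5), and 3 and 8 of 20 inflammatory genes. They numbered 8 and 8 of 18 apoptosis genes (8 and 9), 10 and 8 of 26 glycolysis and hypoxia genes, 3 and 10 of 17 LXR and lipid efflux genes, and 4 and 6 of 17 Runx family genes and partners. Among markers of other cells they numbered 3 and 6 of 13 for progenitors, 1 and 8 of 14 for monocytes, 1 and 8 of 15 for neutrophil granules (1 and 9), 2 and 0 of 11 for stromal cells and osteoblasts (1 and 0), and 2 and 2 of 5 for erythroid cells and megakaryocytes. They numbered 7 and 3 of 20 stress genes (7 and 2) and 0 and 0 of 5 sex-linked genes. Where no second pair is given, the counts adjusted over the list alone were equal. Median, mean and test differed in sign for alternative activation (−0.83, 0.10, down), apoptosis (−0.29, 0.27, up), the Runx family (−0.08, 0.46, down), erythroid cells (0.01, −0.98, down) and the sex-linked genes (0.00, 0.34, down). Lists with fewer than 5 tested members had no list test: 1 of 2 mast cell and basophil genes fell, 3 of 4 lymphoid genes fell and 2 of 3 transgene locus genes fell, with 0 rises in each.

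**Figure D2:**
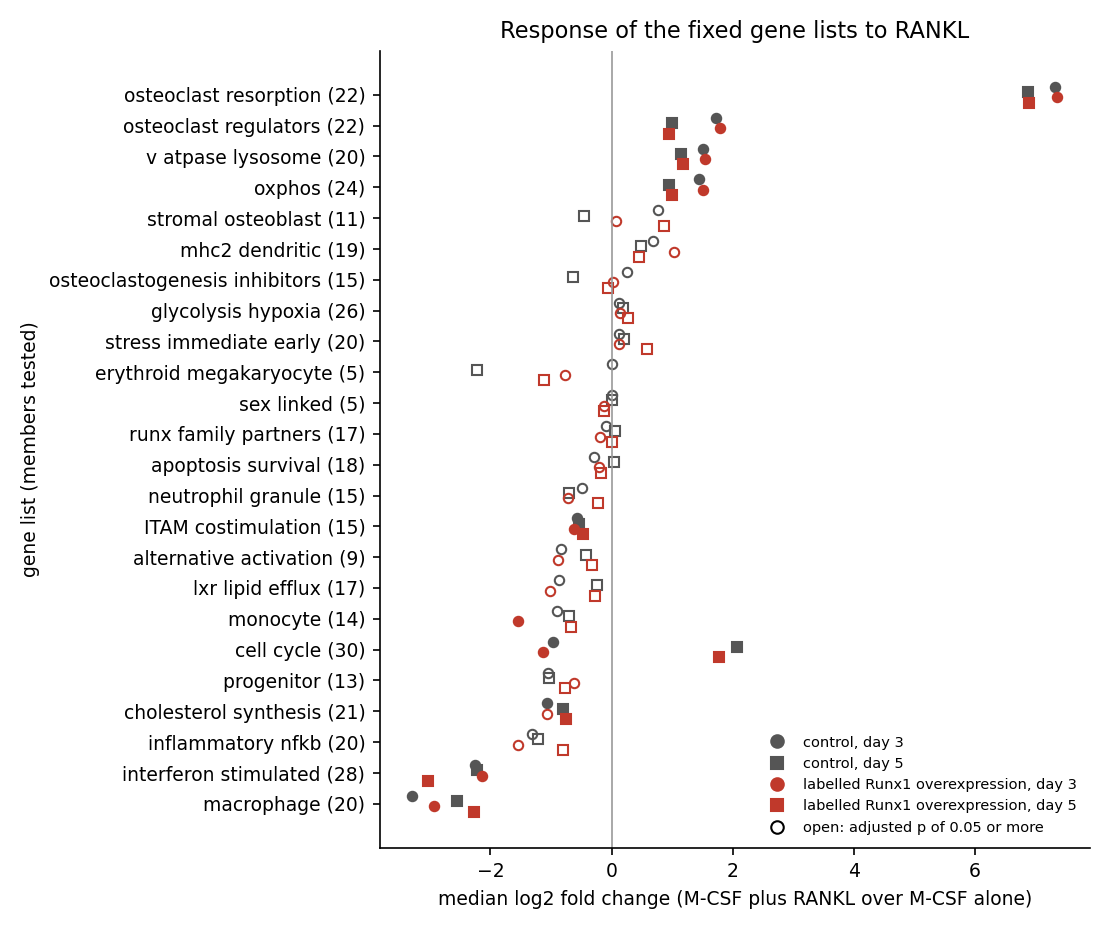
Median log2 fold change of the members of each fixed gene list (horizontal axis) for M-CSF plus RANKL against M-CSF alone, with the number of tested members beside each list name (vertical axis); grey is control, red is labelled Runx1 overexpression, circles are day 3, squares are day 5, and filled symbols passed the camera test at a preset correlation. Osteoclast resorption genes stand apart with medians from 6.88 to 7.37, and the cell cycle list moves from −0.97 in control cells at day 3 to 2.07 at day 5.

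At day 5 the osteoclast transcripts of control cells were still far above those in M-CSF alone, and cell cycle genes now lay above them too. Ctsk stood at 11742 ± 328 CPM against a mean of 1.90 CPM in M-CSF alone (log2 fold change 12.59, SE 0.32, adjusted p = 1.09e-16) and Acp5 rose by 10.59 (SE 0.31). Oscar and the metallothionein gene Mt3 had 0 counts in M-CSF alone and rose at least 5209-fold and 4343-fold. The mitotic cyclin gene Ccnb2 rose 14.5-fold, to 57.9 ± 1.66 CPM, the kinetochore gene Cenpf by 3.84 (SE 0.26) and Mki67 by 2.39 (SE 0.24). From day 3 to day 5 these genes changed by −4.52, −4.10 and −2.84 log2 units in M-CSF alone. With RANKL they changed by 0.57, 1.44 and 0.97, so most of the shift lay in M-CSF alone. Macrophage genes fell. The organic anion carrier gene Slco2b1 fell by 9.18 (SE 0.70), Rnase4 by 6.70 (SE 0.39), the Fc receptor-like gene Fcrls by 7.03 (SE 0.54), the haemoglobin scavenger receptor Cd163 by 6.28 (SE 0.48) and Siglec1 by 5.86 (SE 0.58). In total 7434 genes passed, 3966 higher and 3468 lower.

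Of the lists at day 5 in control cells, osteoclast resorption (21 of 22 up, 0 down), osteoclast regulators (14 of 22 up, 1 down) and oxidative phosphorylation (24 of 24 up) rose, with the same counts adjusted over the list alone. Their adjusted p were 1.07e-66, 2.73e-06 and 7.00e-13, against adjusted p = 0.000137, adjusted p = 0.0421 and adjusted p = 0.245 with an estimated correlation. Ndufv1 rose 2.62-fold. Cell cycle genes rose in 20 of 30 cases and fell in 1 (20 and 1 adjusted over the list alone, adjusted p = 5.01e-12; adjusted p = 0.471 with an estimated correlation). The proton pump and lysosome list had 13 rises and 6 falls among 20 (14 and 6 adjusted over the list alone, adjusted p = 0.00275; adjusted p = 0.575 with an estimated correlation). Falls numbered 19 of 20 macrophage genes (19 adjusted over the list alone, adjusted p = 7.62e-14; adjusted p = 0.101 with an estimated correlation) and 24 of 28 interferon-stimulated genes (25 adjusted over the list alone, adjusted p = 2.86e-06; adjusted p = 0.575 with an estimated correlation), with 0 rises in both lists. The antiviral GTPase gene Mx1 changed by −4.15 (SE 0.79, adjusted p = 0.000196). ITAM costimulation had 9 falls and 2 rises among 15 (10 and 2 adjusted over the list alone, adjusted p = 0.0190; adjusted p = 0.471 with an estimated correlation), and cholesterol synthesis 12 falls and 0 rises among 21 (12 and 0 adjusted over the list alone, adjusted p = 0.0135; adjusted p = 0.708 with an estimated correlation). The other 15 tested lists had adjusted p between 0.127 and 0.924, and median, mean and test differed in sign for the MHC class II, progenitor, stromal and stress lists. Runx1 fell by 0.63 log2 units (SE 0.14, adjusted p = 0.000635).

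In the libraries labelled Runx1 overexpression RANKL moved largely overlapping sets of genes. At day 3 Mmp9 rose from 4.77 ± 0.959 to 26891 ± 5138 CPM (log2 fold change 12.46, SE 0.32) and Ctsk by 11.32 (SE 0.30). The fusion gene Ocstamp and the costimulatory receptor Tnfrsf9 had 0 counts in M-CSF alone and rose at least 11687-fold and 1202-fold, while Slco2b1 fell by 6.32 (SE 0.58) and the scavenger receptor Marco by 5.98 (SE 0.49). At day 5 Ctsk rose by 12.21 (SE 0.31), Calcr by at least 3647-fold and Ccnb2 by 3.29 (SE 0.15), and Fcrls, Ms4a4a and Siglec1 fell by 7.48 (SE 0.56), 7.43 (SE 0.85) and 5.99 (SE 0.59). The counts were 8903 genes at day 3 (4372 higher, 4531 lower) and 7885 at day 5 (4138 higher, 3747 lower). Of the genes called higher at day 3, 3975 were shared with control cells (1288 for independent lists), and of those called lower, 3978 (1344 for independent lists), with 0 in opposite directions. At day 5 the shared calls were 3459 (1092) and 3061 (864), with 1 gene in opposite directions. Across all 15035 genes, which are not independent replicates, the fold changes of the genotypes correlated with r = 0.944 at day 3 and r = 0.923 at day 5. Runx1 fell by 0.57 at day 3 (SE 0.14, adjusted p = 0.00113) and by 0.40 at day 5 (SE 0.14, adjusted p = 0.0179). The last call is lost without library number 3 of the RANKL group, where the change is −0.27.

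The lists moved in these libraries as follows. At day 3 the rises numbered 21 of 22 for osteoclast resorption (adjusted p = 3.27e-55; adjusted p = 0.00049 with an estimated correlation) and 14 of 22 for osteoclast regulators, of which 2 fell (2.63e-08; adjusted p = 0.00623 with an estimated correlation). They numbered 24 of 24 for oxidative phosphorylation (1.66e-21; adjusted p = 0.0934 with an estimated correlation) and 13 of 20 for the proton pump and lysosome, of which 6 fell (0.00489; adjusted p = 0.664 with an estimated correlation). The falls numbered 17 of 20 macrophage genes with 1 rise (1.11e-09; adjusted p = 0.127 with an estimated correlation) and 23 of 28 interferon-stimulated genes (0.000365; adjusted p = 0.763 with an estimated correlation). They also took in 24 of 30 cell cycle genes (6.30e-05; adjusted p = 0.742 with an estimated correlation), 9 of 15 ITAM genes with 2 rises (0.00809; adjusted p = 0.399 with an estimated correlation) and 10 of 14 monocyte genes with 1 rise (0.0477; adjusted p = 0.425 with an estimated correlation). Counts adjusted over the list alone differed only for the proton pump list (14 and 6), interferon (24 falls) and ITAM (10 falls and 3 rises). At day 5 the rises numbered 21 of 22 resorption genes (6.74e-67; adjusted p = 0.000263 with an estimated correlation) and 15 of 22 regulators with 1 fall (1.03e-06; adjusted p = 0.0375 with an estimated correlation). Rises also numbered 24 of 24 oxidative phosphorylation genes (2.52e-13; adjusted p = 0.236 with an estimated correlation), 20 of 30 cell cycle genes with 1 fall (3.03e-09; adjusted p = 0.587 with an estimated correlation) and 13 of 20 pump and lysosome genes with 6 falls (0.00239; adjusted p = 0.587 with an estimated correlation). The falls at day 5 numbered 17 of 20 macrophage genes (2.52e-11; adjusted p = 0.182 with an estimated correlation) and 26 of 28 interferon-stimulated genes (5.54e-09; adjusted p = 0.587 with an estimated correlation). Falls also numbered 10 of 15 ITAM genes with 2 rises (0.0123; adjusted p = 0.467 with an estimated correlation) and 11 of 21 cholesterol synthesis genes (0.0238; adjusted p = 0.812 with an estimated correlation). Adjusted over the list alone, macrophage falls became 18 and pump rises 14, and the other counts of these lists were equal. Median, mean and test differed in sign for alternative activation, the Runx family and stress at day 3, and for the apoptosis and progenitor lists at both days.

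Whether the response to RANKL differed between the genotypes was tested gene by gene. The edgeR test called 0 genes at day 3 and 0 at day 5, and DESeq2 called 0 and 0. By edgeR 242 and 481 genes had an unadjusted p under 0.05, where 752 are expected by chance. Counts below that may mean that the test was conservative here, so 0 calls do not show that the responses were equal. With the 4 libraries of number 3 labelled Runx1 overexpression left out, a choice made after the data were seen, edgeR called 7 genes at day 5. At day 3, 0 lists passed, and 4 did without control library number 3 in M-CSF alone. Adjusted over the list alone, 1 osteoclast resorption gene had a higher response at day 3 in the libraries labelled Runx1 overexpression. At day 5, 7 lists passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.475), and 0 of their members passed over all genes or adjusted over the list alone. Without control library number 1 in M-CSF alone 3 lists passed at day 5. In the interferon-stimulated list 0 of 28 members had a positive difference, with a mean of −0.92 (adjusted p = 2.70e-07; adjusted p = 0.683 with an estimated correlation).

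**Figure D3:**
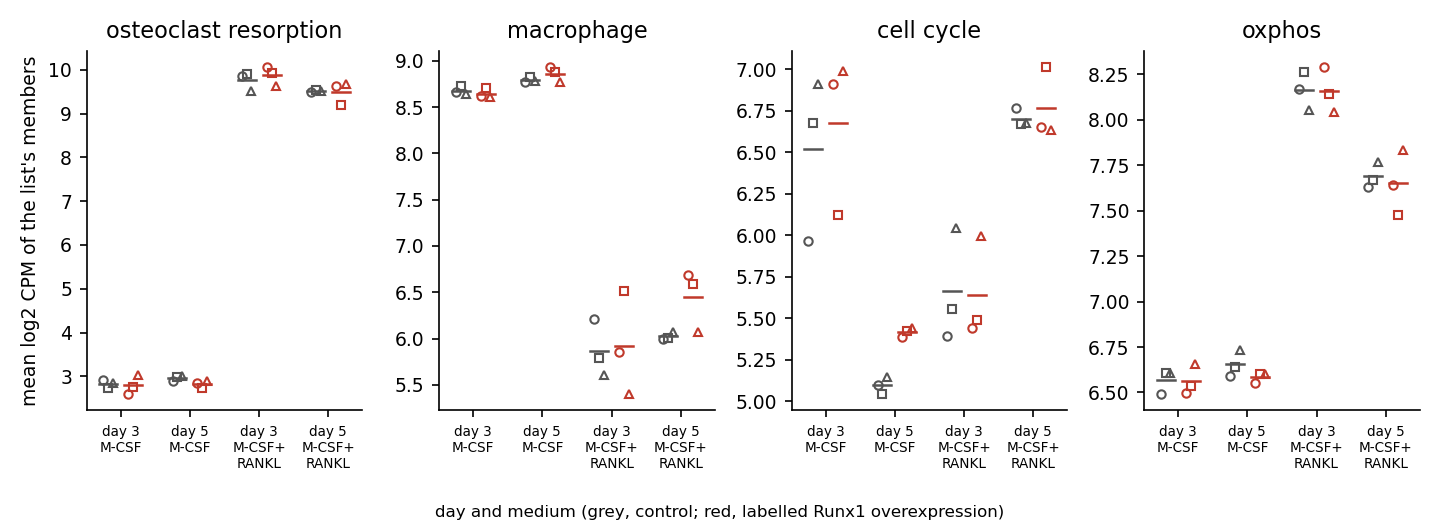
Mean log2 CPM of the tested members of the osteoclast resorption, macrophage, cell cycle and oxidative phosphorylation lists (vertical axes, not starting at 0) in each of the 24 libraries by day and medium (horizontal axes); grey is control, red is labelled Runx1 overexpression, marker shape is the number in the label and short lines are group means of 3 libraries. Cell cycle transcripts are lowest at day 5 in M-CSF alone, where 19 of 30 members fell from day 3 in each genotype, and oxidative phosphorylation transcripts are highest at day 3 with RANKL.

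From day 3 to day 5 under RANKL, which follows the maturing osteoclasts, most oxidative phosphorylation genes fell and most cell cycle genes rose in both genotypes. In control cells Fosl1, an AP-1 factor, rose from 0.502 ± 0.438 to 13.6 ± 2.30 CPM (log2 fold change 4.77, SE 0.60, adjusted p = 1.6e-05) and the neuropeptide gene Npy from 2.87 ± 0.630 to 42.0 ± 1.44 CPM (3.87, SE 0.22). The desaturase gene Scd2 fell from 622 ± 67.9 to 38.3 ± 2.44 CPM (−4.02, SE 0.48) and the granulocyte peroxidase gene Mpo by 3.55 (SE 0.56). Among oxidative phosphorylation genes 21 of 24 fell in control cells and 22 of 24 in the libraries labelled Runx1 overexpression, with 0 rises (22 and 22 falls adjusted over the list alone), and Ndufv1 changed by −0.60 (SE 0.09) in control cells. Cell cycle genes rose in 21 and 24 of 30 cases with 0 falls (26 and 28 adjusted over the list alone). In the libraries labelled Runx1 overexpression Fosl1 rose by 5.50 (SE 0.63) and Scd2 fell by 4.16 (SE 0.49), and Bach2, a repressor of immune differentiation, fell by 3.08 (SE 0.28). Rises there included the matrix genes Ctgf at 6.08 (SE 1.02), Col12a1 at 5.19 (SE 1.10) and Col5a1 at 4.70 (SE 0.99), and their SDs at day 5 were close to the means (19.6 ± 16.1 CPM for Ctgf). Stromal and osteoblast markers rose in 9 of 11 cases in these libraries and in 2 of 11 in control cells (9 and 2 adjusted over the list alone), where the members were Acta2 at 2.91 (SE 0.79) and Dcn at 1.33 (SE 0.43). The Dcn call is lost without library number 1 (1.12) or 2 (1.32) of day 3 or number 2 (1.09) or 3 (1.42) of day 5, and the Acta2 call without number 1 of day 3 (2.77). Acta2, a smooth muscle actin gene, rose by 4.56 (SE 0.82) in the libraries labelled Runx1 overexpression, to 39.0 ± 30.3 CPM.

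In total 4027 genes changed with day in control cells, 2114 higher and 1913 lower, and 4995 in the libraries labelled Runx1 overexpression, 2651 higher and 2344 lower. With RLE scaling the lower calls outnumbered the higher ones, at 1759 higher and 2342 lower in control cells and 2374 and 2691 in the others. Shared calls numbered 1854 higher (373 for independent lists) and 1577 lower (298), with 1 in opposite directions, and r across genes was 0.771. The test of the difference between genotypes called 0 genes with edgeR (225 at an unadjusted p under 0.05, against 752 expected by chance) and 0 with DESeq2. Here too the test may have been conservative, so the time courses cannot be called equal. Without library number 1 of the control group at day 5 the control count falls to 2614, and without library number 2 of the other genotype at day 5 its count falls to 3316. Runx1 rose by 0.41 in control cells (SE 0.14, adjusted p = 0.0302), a call lost with RLE scaling, with DESeq2 (0.36 in both) and on leaving out any 1 of the 6 libraries compared (0.38 to 0.43). It rose by 0.48 in the other genotype (SE 0.14, adjusted p = 0.0109), a call lost without library number 2 of day 5 (0.37), number 1 of day 3 (0.42) or number 3 of day 3 (0.41).

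The comparison of the genotypes asks what LysM-Cre together with the Runx1 transgene did to macrophages and osteoclasts, against the transgene without Cre. No group carried Cre alone. Effects of Runx1, of Cre and of its insertion at Lyz2 therefore cannot be told apart. With edgeR on all libraries no osteoclast gene passed over all genes. Adjusted over the list alone, 1 resorption gene, Mmp9, was lower in M-CSF alone at both days. DESeq2 called Mmp9 lower over all genes at day 5 in M-CSF alone. The resorption list had adjusted p of 0.813 and 0.0563 at day 3 in M-CSF alone and with RANKL, and 0.0932 and 0.692 at day 5. With RANKL at day 5, Ctsk stood at 11742 ± 328 CPM in control cells and 11774 ± 2394 CPM in the libraries labelled Runx1 overexpression, and the interval of the log2 difference was −0.39 to 0.40. In M-CSF alone at day 5, Mmp9 was at 12.7 ± 4.09 against 23.9 ± 2.98 CPM in controls (log2 difference −0.91, SE 0.21, adjusted p = 0.433), the mitotic checkpoint gene Bub1b at 26.6 ± 1.14 against 18.1 ± 1.56 CPM (0.55, SE 0.14, adjusted p = 0.509) and the adhesion gene Nectin1 at 5.84 ± 1.58 against 2.70 ± 0.606 CPM (1.11, SE 0.18, adjusted p = 0.0688, the lowest of any gene and genotype comparison). With RANKL at day 5 the neutrophil granule gene Ngp was at 42.2 ± 3.20 against 25.2 ± 4.34 CPM (0.74, SE 0.16, adjusted p = 0.922). The receptor gene Axl, which takes part in the uptake of dying cells, was at 41.7 ± 29.7 against 12.4 ± 1.69 CPM (1.74, SE 0.43, adjusted p = 0.996). Without library number 1 of the libraries labelled Runx1 overexpression the Axl difference is 1.07 and without number 3 it is 2.19.

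By edgeR 0 genes passed in each of the 4 genotype comparisons. The numbers at an unadjusted p under 0.05 were 530 and 258 at day 3 in M-CSF alone and with RANKL, and 948 and 457 at day 5, where 752 are expected by chance. Those below 752 may mean a conservative test, so 0 calls do not show that the genotypes were equal. DESeq2 called 3 genes (Afdn and Nectin1 higher, Ndrg4 lower), 1 gene (Cacna1a lower), 18 genes and 5 genes (Axl, Cd244a, F7, Ngp and Slco2b1, all higher) in the same order. The interval of the log2 difference lay within 1 unit either way for 71.0%, 71.3%, 69.2% and 70.6% of tested genes. A single set of libraries bore on these counts. With the 4 libraries of number 3 labelled Runx1 overexpression left out, a choice made after the data were seen, edgeR called 35, 6, 110 and 39 genes. Leaving out only its library at day 5 in M-CSF alone gave 22 genes there, and its library at day 5 with RANKL gave 7.

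At the preset correlation, lists passed that did not with an estimated one. At day 3 in M-CSF alone the monocyte and cell cycle lists were higher in the libraries labelled Runx1 overexpression (adjusted p = 0.0439 each; adjusted p = 0.964 with an estimated correlation), and at day 3 with RANKL 0 lists passed. At day 5 in M-CSF alone 8 lists passed. Higher were cell cycle (29 of 30 members positive, median 0.29, adjusted p = 2.12e-09; adjusted p = 0.542 with an estimated correlation), interferon-stimulated (28 of 28 positive, median 0.52, adjusted p = 6.56e-05; adjusted p = 0.676 with an estimated correlation), monocyte (0.00857; adjusted p = 0.412 with an estimated correlation) and neutrophil granule (0.0375; adjusted p = 0.542 with an estimated correlation). Lower were glycolysis and hypoxia (1 of 26 positive, adjusted p = 4.47e-05; adjusted p = 0.542 with an estimated correlation), stress (0.000656; adjusted p = 0.403 with an estimated correlation), erythroid (0.0104; adjusted p = 0.251 with an estimated correlation) and cholesterol synthesis (0.0233; adjusted p = 0.676 with an estimated correlation). At day 5 with RANKL 6 lists passed. Higher were neutrophil granule (13 of 15 positive, median 0.56, adjusted p = 2.04e-09; adjusted p = 0.0558 with an estimated correlation), macrophage (19 of 20 positive, median 0.31, adjusted p = 3.28e-09; adjusted p = 0.441 with an estimated correlation), stromal (median 1.51, adjusted p = 0.00101; adjusted p = 0.441 with an estimated correlation) and monocyte (0.0348; adjusted p = 0.441 with an estimated correlation). Lower were glycolysis and hypoxia (0.000125; adjusted p = 0.441 with an estimated correlation) and interferon-stimulated (3 of 28 positive, adjusted p = 0.0191; adjusted p = 0.853 with an estimated correlation). Median, mean and test differed in sign in none of these lists. They did among lists that did not pass, such as osteoclast resorption at day 3 in M-CSF alone (0.06, −0.01, down) and at day 5 with RANKL (−0.02, 0.01, down). Over all genes 0 members passed. Adjusted over the list alone 2 members passed at day 3 in M-CSF alone, 0 at day 3 with RANKL, 5 at day 5 in M-CSF alone and 12 at day 5 with RANKL, of which 6 were neutrophil granule genes, Ngp among them, and 4 macrophage genes, Axl among them. Leaving out a single library moved the number of lists. At day 3 in M-CSF alone it was 1 without control number 2 and 4 without number 3 labelled Runx1 overexpression, and with RANKL it was 6 without the latter. At day 5 it was 4 in M-CSF alone without control number 3, and 11 with RANKL without number 3 labelled Runx1 overexpression.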

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

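The tests of the lists at day 5 between genotypes were planned, and the tests of how the RANKL response differs between days were chosen after the data were seen.

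The RANKL response at day 5 differed between genotypes for 7 lists at the preset correlation, which is what marked them here. The macrophage (adjusted p = 0.000232; 0.683 with an estimated correlation), inflammatory (0.0268; 0.647), neutrophil granule (0.0395; 0.683), erythroid and megakaryocyte (0.0268; 0.475) and stress (0.0111; 0.647) lists had a higher response in the libraries labelled Runx1 overexpression. The interferon-stimulated (2.70e-07; 0.683) and cell cycle (5.83e-05; 0.768) lists had a lower one, as the interferon genes lay higher in M-CSF alone and lower with RANKL in those libraries. Of their members 0 passed over all genes and 0 adjusted over the list alone. In 30 splits of the libraries, the planned one among them, 15 called at least as many lists, with up to 13 in another split against the real 7. Chance can therefore not be excluded for these lists.

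The RANKL response differed between day 3 and day 5 for 2103 genes in control cells (1091 with a higher response at day 5, 1012 lower) and for 2288 genes in the libraries labelled Runx1 overexpression (1216 and 1072). Of 30 cell cycle genes, 19 had a higher response at day 5 in each genotype and 0 a lower one (20 and 0 adjusted over the list alone in each). The list gave adjusted p = 5.75e-70 in control cells and 2.81e-63 in the others, with 0.0129 and 0.0201 with an estimated correlation. Oxidative phosphorylation had a lower response at day 5, with 17 and 15 of 24 genes (22 and 20 adjusted over the list alone) and adjusted p = 2.02e-09 and 1.17e-08 (0.588 and 0.691 with an estimated correlation). The osteoclast regulators had a lower response in both genotypes (0.0158 and 0.00719; 0.588 and 0.404 with an estimated correlation). The osteoclastogenesis inhibitors did in control cells (0.0158; 0.588 with an estimated correlation), and the interferon-stimulated genes did in the libraries labelled Runx1 overexpression (0.0317; 0.979 with an estimated correlation).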

How the results depend on the processing

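Leaving out all libraries of a number, in a genotype or in both, and the comparison of RANKL responses between days, were chosen after the data were seen, and the other settings were planned. No named gene that passed reversed its sign, while the larger direction for day did reverse with the scaling, as given below. Of the values for named genes under other settings, with only the lowest and highest taken where single libraries were left out, 609 kept their call or stayed within 1 SE, 10 without a call moved further and 7 lost their call. Over every fit that left out a single library, 15 calls of named genes were lost among 432. Many named genes were chosen for large changes or a small p, which favours their calls, so this share does not describe the other calls. Except where another reason is given, the cause was not tested.

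With DESeq2 the genotype comparisons gave 3, 1, 18 and 5 genes (day 3 in M-CSF alone, day 3 with RANKL, day 5 in M-CSF alone, day 5 with RANKL) in place of 0. Without a filter the comparison at day 5 in M-CSF alone gave 1 gene. With an estimated correlation 0 lists passed for genotype at day 3 in M-CSF alone, at day 5 in M-CSF alone, at day 5 with RANKL, and for the difference of RANKL responses at day 5, and 2 lists passed in each of the RANKL comparisons, osteoclast resorption and regulators.

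With the label number as a block, genotype gave 1 gene at day 3 and 3 at day 5 in M-CSF alone. With RANKL it gave 1 gene at day 5 and 3 lists at day 3. The Y-linked gene Ddx3y was the call at day 3 in M-CSF alone and at day 5 with RANKL. It was also among the 3 at day 5 in M-CSF alone, with Nectin1 and Tnfsf8. Y-linked counts came almost only from number 3 labelled Runx1 overexpression, so the Ddx3y calls rest on that set. For RANKL and day the block was the number within a genotype. It gave 9048, 7650, 9045 and 8062 genes for RANKL (control day 3, control day 5, then the same days in the other genotype). For day it gave 4418 and 5364, and neither block changed any other call. Correlations of same-numbered deviations ran from 0.0984 to 0.324 and from 0.0418 to 0.186 for RANKL in control cells at days 3 and 5. In the other genotype they ran from 0.0770 to 0.313 for RANKL at day 3. They ran from −0.121 to 0.461 for genotype and from 0.00836 to 0.159 for day. Within a genotype each library correlated best with its own number, a hint from the data and not from the design.

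Leaving out 1 library at a time gave 0 to 22 genes for genotype at day 5 in M-CSF alone (22 without number 3 labelled Runx1 overexpression) and 0 to 7 at day 5 with RANKL (7 without number 3 of the same genotype). It gave 2614 to 4032 genes for day in control cells and 3316 to 4913 in the other genotype. Lists passed for genotype numbered 1 to 4 and 1 to 6 at day 3 (M-CSF alone, RANKL), 4 to 12 and 5 to 11 at day 5, and for the difference of responses 0 to 4 at day 3 and 3 to 9 at day 5.

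Leaving out all 4 libraries of number 3 labelled Runx1 overexpression gave 35, 6, 110 and 39 genes for genotype, 7 for the difference of RANKL responses at day 5, and 4 and 6 lists for genotype at day 3 in M-CSF alone and with RANKL and 7 for the difference of responses at day 3. Without number 1 of that genotype day gave 2610 genes, and the lists were 4 and 3 for genotype at day 3 and 4 for the difference at day 5. Without number 2 of it day gave 2549 genes, and the lists were 2 at day 3 with RANKL, 4 at day 5 in M-CSF alone and 1 for the difference at day 3. Without control number 1 there were 3 genes for genotype at day 5 in M-CSF alone, 1855 for day, and 5, 2 and 3 lists for genotype at day 3 with RANKL and the differences at days 3 and 5. Without control number 2 there were 1309 genes for day, 1 list for genotype at day 3 with RANKL and 2 for the difference at day 3. Without control number 3 there were 2 lists for genotype at day 3 with RANKL and 4 at day 5 in M-CSF alone. Without number 3 of both genotypes 9, 3, 86 and 37 genes passed for genotype, and without number 1 or number 2 of both genotypes 0 passed in each comparison. Each of these fits tests fewer libraries, which by construction lowers the power for day.

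With RLE scaling the day comparison had more lower than higher calls (1759 higher and 2342 lower in control cells, 2374 and 2691 in the other genotype), and with DESeq2 too (1942 and 2603, 2528 and 2947), so the larger direction for day depends on the scaling. A single read was worth 0.0286 to 0.0542 CPM, which limits what can be said of genes near that level.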

Other observations

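In M-CSF alone, from day 3 to day 5, 3570 genes changed in control cells (1838 higher, 1732 lower) and 2143 in the libraries labelled Runx1 overexpression (1078 higher, 1065 lower), a comparison chosen after the data were seen, as were all tests on left-out cultures below. Cell cycle genes fell. In control cells the cyclin gene Ccnb2 fell by 4.52 log2 units (SE 0.16), Cenpf by 4.10 (SE 0.26), the kinesin gene Kif20a by 3.26 (SE 0.17), the mitotic kinase gene Plk1 by 3.10 (SE 0.20) and Mki67 by 2.84 (SE 0.24), and 19 of 30 cell cycle genes fell in each genotype, while 2 rose in control cells and 0 in the others (adjusted over the list alone 19 fell in each, and 2 and 1 rose). With RANKL the same genes rose over these days, Ccnb2 by 0.57 and Cenpf by 1.44 in control cells. The difference between the media was 5.09 (SE 0.21, adjusted p = 2.31e-12) for Ccnb2 and 5.54 (SE 0.34) for Cenpf, and 4.57 (SE 0.21) and 4.82 (SE 0.33) in the libraries labelled Runx1 overexpression. Of genes that act in DNA replication, picked after the data were seen, the difference was −0.15 (SE 0.48, adjusted p = 0.886) for Mcm6 and 0.43 (SE 0.37, adjusted p = 0.502) for Pcna in control cells, and the group was not tested. In M-CSF alone Mmp9 rose by 1.40 (SE 0.22) and Ctsk fell by 1.06 (SE 0.26) in control cells.

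Without the 4 libraries of number 3 labelled Runx1 overexpression, genes passed between genotypes in all 4 conditions (35, 6, 110 and 39). Padi2, a citrullinating enzyme gene, passed in all of them and rose by 1.37 log2 units at day 3 and 2.40 at day 5 in M-CSF alone and by 2.06 at day 5 with RANKL, and Lyz1, Wdfy1 and 2010005H15Rik also rose in all 4, while Sel1l3 fell in all 4. The conditions compare the same numbered sets, and same-numbered libraries of a genotype deviated together. Passing in all 4 may therefore not be independent repeats. With RANKL at day 5 the rises included Slco2b1 at 3.91, Cd163 at 2.19, Axl at 2.17, the adhesion gene Vcam1 at 2.69 and the chemokine receptor Cx3cr1 at 1.90. The first 2 were low. In numbers 1 and 2 Slco2b1 was at 5.37 and 1.66 CPM (control mean 0.232) and Cd163 at 4.45 and 2.75 CPM (control mean 0.793). In M-CSF alone Mmp9 fell by 1.10 at day 3 (adjusted p = 0.0457) and by 1.18 at day 5 (adjusted p = 0.00766), and the related factor Runx3 fell by 3.28 and 2.83. The libraries of number 3 deviated together across genotypes, with correlations of 0.461, 0.361, 0.206 and 0.145, against −0.121 to 0.0429 for numbers 1 and 2. With number 3 left out of both genotypes 9, 3 (Padi2 and Wdfy1 higher, Sel1l3 lower), 86 and 37 genes passed. The 9 at day 3 in M-CSF alone held neither Mmp9 nor Runx3. There Runx3 was at 0.402 and 0.279 CPM in numbers 1 and 2, against 0.699, 3.78 and 5.44 CPM in the controls. Of the genes given next, all but Lyz2 were chosen for a difference between genotypes in fits with or without number 3. The levels of these chosen genes in number 3 therefore decide nothing about its label. Of genes from fits without it, Padi2 in number 3 was at 24.02, 83.6, 9.12 and 74.7 CPM against control means of 23.4, 86.7, 11.2 and 81.4 CPM, and Lyz1 at 7.39, 0.888, 5.67 and 2.51 CPM against 8.24, 1.38, 6.27 and 2.12 CPM. Of genes from fits with it, Nectin1 in number 3 was at 4.28, 32.1, 4.02 and 39.7 CPM against control maxima of 2.82, 25.9, 3.39 and 27.9 CPM, and Cacna1a at 40.1, 8.38, 74.3 and 11.5 CPM against control minima of 48.5, 10.5, 105 and 20.01 CPM. Lyz2, taken in each comparison by rule, was in number 3 at 0.772, 0.673, 1.07 and 1.07 of the control mean. The mean of numbers 1 and 2 was at 0.601, 0.608, 0.614 and 0.643 of it, and no Lyz2 difference was called. Lyz2 in number 3 lay below every control at day 3 and within their range at day 5. It was close to control number 3 in each condition, at 15941 against 16484, 2042 against 2124, 23410 against 23695 and 5196 against 5240 CPM. At day 3 with RANKL number 2 labelled Runx1 overexpression was higher than number 3, at 2518 CPM. On its own this gene does not settle the label.

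Calls between genotypes appear when number 3 labelled Runx1 overexpression is left out. Leaving out any of the other 5 numbered sets gave at most 3 calls over the 4 comparisons, against 190, which excludes a general effect of leaving out libraries. If number 3 were a control under a wrong label, it would lie with the controls on genes chosen without it, and its mean slope on the shift of numbers 1 and 2 was 0.0872 (−0.0705 to 0.210) against 0.203 (−0.0616 to 0.544) for held-out controls. Its slope was above that of the held-out control in 3 of 12 comparisons and at day 3 with RANKL below all of them (0.108, 0.153 and 0.210 against 0.484, 0.262 and 0.268), and a set that differs for another reason could give such slopes, so the question stays open. It may also be a difference of sex, since number 3 alone carried Y-linked transcripts and almost no Xist. With 0 control sets that carry Y-linked transcripts the design cannot separate these. Nor can it rule out, for part of the calls, a structure that the libraries of number 3 share.

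Runx1 was not called higher in the libraries labelled Runx1 overexpression, although at day 3 with RANKL all 3 of them (52.7 to 67.4 CPM) lay above the 3 controls (50.6 to 52.4 CPM), which chance gives in 10% of such groups in either direction. Number 3 alone does not hide a doubling, since without it the highest upper end of the intervals of the Runx1 log2 difference was 0.649, at day 5 with RANKL, where the difference was 0.37 with a lower end of 0.10 (adjusted p = 0.387). A transgene expressed only at the level of the Rosa26 transcript could add too little to see, as that transcript reached at most 13.5% of Runx1 in control groups and the intervals allow rises of 21.8% to 42.8%. This stays open, since the level of the transgene itself was not measured here, and no biological explanation was tested.

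Lyz2 was lower and Lyz1 higher in numbers 1 and 2 labelled Runx1 overexpression, with Lyz1 up by 2.12, 2.60, 2.34 and 3.05 log2 units and Lyz2 at −0.74, −0.71, −0.71 and −0.64, where the Lyz2 adjusted p were 0.567, 0.984, 0.422 and 0.658. A fixed share of Lyz2 reads assigned to the near-identical Lyz1 would move both genes the same way, but a small change of that share could raise Lyz1, whose gain was at most 0.896% of the loss of Lyz2, so misassignment stays open. Alleles that travel with the Cre insertion at Lyz2 could shift its neighbours, but the 100 genes with the smallest p held 1 to 2 within 20 Mb of Lyz2 against 1.15 expected (p = 0.685 in M-CSF alone and 0.318 with RANKL at both days in an exact hypergeometric test). These were Lyz1 in each condition and Suox with RANKL. Suox rose by 1.30 at day 3 (adjusted p = 0.0289) and by 1.79 at day 5 (adjusted p = 0.000516). Both genes were among only 6 called at day 3 with RANKL, so most of the 100 genes there were not called. The upper limit of the share within 20 Mb, 7.04%, leaves room for an excess of several fold, so this stays open, a judgement made after the result was seen. No biological explanation was tested.

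Splits of the same 6 libraries into other groups of 3 number 10 with the planned one, too few for a share under 0.05. For genotype, the real count is 0 genes in each comparison, which all 10, 10, 10 and 10 splits reach by construction (day 3 in M-CSF alone, day 3 with RANKL, day 5 in M-CSF alone, day 5 with RANKL), with 2546, 48, 1 and 0 as the highest other counts. The 2546 genes of a split at day 3 in M-CSF alone point to a structure of these libraries other than genotype. For RANKL, 1 of 10 splits in each comparison reached the real count (8888, 7434, 8903 and 7885), with 0 in every other. For day, 1 of 10 splits reached the real 4027 in control cells and 1 of 10 the real 4995 in the other genotype, with 1 and 6 as the highest other counts. For lists, 8, 10, 2 and 7 of 10 splits reached the real 2, 0, 8 and 6 for genotype (the 0 by construction, highest other 6, 12, 8 and 10), and 2, 7, 4 and 5 reached the real 9 for RANKL (highest other 10, 12, 11 and 10). For the differences of responses between genotypes, the real counts of 0 genes at day 3, at day 5 and for day and of 0 lists at day 3 are reached by 30 of 30 splits by construction, so these splits test nothing there. The highest others were 3878, 2 and 2 genes and 10 lists, and the 3878 genes of a split at day 3 again point to a structure of the libraries.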
